A study of Mus musculus with 7 samples.

How the data were processed

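The samples were 7 libraries of mRNA from CD19-positive, mCherry-positive, FluoroGold-negative (live) cells, sorted from host blood by flow cytometry, per the labels' protocols. Blood was drawn into EDTA and red cells were removed before sorting. Cell pellets were frozen, and all RNA was then prepared together, per the labels' protocols. A genome facility made and sequenced the libraries with Illumina protocols. The deposited values are raw counts of reads per gene, with no normalization, in a series table and in 7 single-sample tables. Per the submitters' processing notes, reads were handled with bcl2fastq 2.19.1.403, aligned to mm10 with STAR 2.5.3a and counted with featureCounts, whose version is not stated. Strand, the annotation release and any filter on reads are not stated, so overlapping and antisense genes cannot be told apart. The deposited tables also give a length for each gene, which was not used in any test. The 7 single-sample tables were checked and were identical to the columns of the series table. No pair among 21 pairs of libraries looked like a duplicate, since the lowest chi-square per degree of freedom was 3.22 over genes with at least 20 counts.

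The table held 27179 gene IDs. Symbols and coordinates came from a RefSeq gene table of GRCm38.p6, which matched 25275 IDs, and from GENCODE M21, which matched 18 more. Together, 93.1% of IDs had a symbol and 1886 had none. Library totals were 10859727 to 13214986 counts, and a gene at 0 was given a floor of 3 counts. CPM were computed from the counts with TMM-scaled library sizes, and shares of single libraries were given 95% Wilson intervals.

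Genes were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests on TMM-normalized counts after filterByExpr by host genotype, with Benjamini-Hochberg adjusted p of 0.05 as the threshold. Hosts were compared with collection day as a covariate, over 3 TpoTg and 4 WT libraries. The days were compared in the same fit, over 2 libraries at day 15 and 5 at day 19. Host sexes were compared with day and genotype as covariates, over 4 female and 3 male hosts, and the change of the host effect between days was tested as an interaction. Residual degrees of freedom were 4 for hosts and days and 3 for sexes and the interaction. Within-day values are the log2 ratio of the day 15 pair, which has no replicates, and a fit of day 19 alone.

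A set of 35 gene lists with 516 entries was written before the data were examined, as were the comparisons, the rule for naming genes and the alternatives below unless said otherwise. They cover cell types of the blood and pathways, and 4 entries matched no ID (Hbb-bt, Ahsp, Rn7s1 and Rn7s2). Lists with at least 3 tested members, 33 of them, were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. The fry test was run as a self-contained test, and p values were adjusted over the lists. The text names genes by a rule. In the host comparison, where fewer than 10 genes passed, it names the 10 with the smallest p. Between days it names the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM. Between sexes, where fewer than 6 passed, it names the 6 with the smallest p. From each list it draws on up to 4 members with the smallest p in the host comparison, and it adds a fixed set of check genes. Genes without a symbol and predicted genes were counted and not named unless first in a direction. Genes named outside the rule are said to be chosen after their values were seen.

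The tests were first run on simulated data, drawn from the means and dispersions of the 11220 tested genes with 200 genes changed. For the host comparison, 92 of 100 genes changed by 2-fold and 76 of 100 changed by 1.5-fold were recovered, with 11 false genes among 179 calls. For the day comparison, 90 of 100 and 76 of 100 were recovered, with 13 false genes among 179 calls. When the platelet list was raised by 2-fold, camera called it, with an adjusted p of 2.40e-33 and with 0.0063 under an estimated correlation, and fry gave 0.0045, with 0 of 31 other lists called. The simulated genes were drawn independently, whereas the real platelet list had an estimated correlation of 0.404 between hosts. The simulation therefore does not measure false calls of lists whose genes are correlated. Single values were compared between hosts with 2-sided exact permutation tests.

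Alternatives were other scalings (RLE and upper quartile factors), DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter (at least 1 CPM in at least 3 libraries and a mean of at least 5 CPM), immunoglobulin and T cell receptor segments left out, other covariates, day 19 alone, female hosts alone, a robust fit, and each library left out in turn. The share of mitochondrial rRNA as a covariate, the fit without WT 381 with host sex, the day lists without each library or within females, and the lists on the interaction were added after the data were seen. No library was left out of the comparisons reported. Between hosts, when 1 day 15 library is left out, the day term takes up the other. Such a fit in effect repeats day 19 alone and is not a separate check. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.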

Results

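RNA was sequenced from lymphoma cells recovered from the blood of 7 mice. The cells were a single mCherry-marked line of Eµ-myc lymphoma, a B cell tumour driven by a Myc transgene under an immunoglobulin enhancer, given to every host by transplant. The hosts were 3 TpoTg mice, which overexpress thrombopoietin (the hormone that drives platelet production), and 4 wild-type (WT) mice. TpoTg host 385 and WT host 384, both female, were bled at day 15. TpoTg host 386 and WT host 375, both female, and TpoTg host 378, WT host 377 and WT host 381, all male, were bled at day 19. Total counts per library were 11390468 for TpoTg 385, 10971215 for TpoTg 386, 10859727 for TpoTg 378, 12856241 for WT 384, 13214986 for WT 375, 13141498 for WT 377 and 11660711 for WT 381. Between 14387 and 14751 genes had a count in each library. A count of 0 allowed up to 3 counts, which was 0.221 to 0.284 CPM (counts scaled to a common library size) across the libraries. These floors, and the intervals given below for shares, cover counting error only. Expression values are CPM, and coordinates are those of GRCm38 (mm10).

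The recovered cells had a B cell profile at both host genotypes. Cd19 was at 939.9 CPM ± 68.0 (SD, n = 3) in TpoTg hosts and 929.9 ± 82.1 (SD, n = 4) in WT hosts, and Cd79a at 691 CPM ± 53.5 (SD, n = 3) in TpoTg hosts and 695 ± 19.4 (SD, n = 4) in WT hosts. Myc was at 1333 CPM ± 187 (SD, n = 3) in TpoTg hosts and 1297 ± 123 (SD, n = 4) in WT hosts. Trp53 was at 222 CPM ± 1.46 (SD, n = 3) in TpoTg hosts and 233 ± 3.74 (SD, n = 4) in WT hosts, whereas Cdkn2a was near the floor, at 0.0907 CPM ± 0.0932 (SD, n = 3) in TpoTg hosts and 0.116 ± 0.0939 (SD, n = 4) in WT hosts. Among the BCL2 family check genes, Mcl1 was at 403 CPM ± 5.67 (SD, n = 3) in TpoTg hosts and 399.6 ± 14.1 (SD, n = 4) in WT hosts, Bcl2l1 at 155 CPM ± 19.2 (SD, n = 3) in TpoTg hosts and 151 ± 9.76 (SD, n = 4) in WT hosts, Bcl2 at 21.4 CPM ± 2.54 (SD, n = 3) in TpoTg hosts and 19.0 ± 1.85 (SD, n = 4) in WT hosts, and Bcl2l11 at 113 CPM ± 4.81 (SD, n = 3) in TpoTg hosts and 120.3 ± 6.61 (SD, n = 4) in WT hosts. Thpo, the gene overexpressed in the hosts and not in the transplanted cells (gene ID 21832, chromosome 16, 20724454 to 20734511), had 0 counts in all 7 libraries. Its receptor gene Mpl was at or near the floor, at 0.188 CPM ± 0.189 (SD, n = 3) in TpoTg hosts and 0.130 ± 0.111 (SD, n = 4) in WT hosts, and so was the T cell gene Cd3e, at 0.120 CPM ± 0.0450 (SD, n = 3) in TpoTg hosts and 0.199 ± 0.204 (SD, n = 4) in WT hosts. Xist was at 1901 to 2721 CPM in every library, male hosts included. The counts of the Y genes summed to 18, 17 and 17 in male hosts 378, 377 and 381 and to 0, 1, 0 and 0 in female hosts 385, 384, 386 and 375. Ddx3y, the Y gene among the check genes, had 0 counts in the 4 female hosts.

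The comparison of TpoTg with WT hosts asked how a host with raised thrombopoietin changes the expression of the lymphoma cells. Platelet transcripts were higher in the TpoTg hosts at day 19, and the genes of DNA replication and of protein folding were slightly lower. P2rx4, P2rx7, Flt3 and Plaur were among 356 genes higher in all 3 TpoTg libraries than in all 4 WT libraries, so this alone does not single them out. No single gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the gene lists that camera called were not called when the correlation between genes was estimated. Of 11220 genes tested, 0 passed, 1134 (10.1%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.0628. DESeq2 called 7 genes and limma-voom 0, with 1143 at an unadjusted p under 0.05. The host groups did not overlap for 795 genes, 7.09% of those tested, where chance gives 5.71%. Of these, 356 were higher and 439 lower in TpoTg hosts.

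The 10 genes with the smallest p in the host comparison did not pass the threshold. Stoml1 (gene ID 69106, chromosome 9, 58253160 to 58262524) was at 51.2 CPM ± 5.74 (SD, n = 3) in TpoTg hosts and 37.8 ± 4.47 (SD, n = 4) in WT hosts. Its log2 fold change was 0.47 (SE 0.0579), with edgeR adjusted p = 0.0628, and it was 0.51 in the day 15 pair and 0.45 at day 19. Chit1 (gene ID 71884, chromosome 1, 134111242 to 134151541) was at 18.3 CPM ± 7.15 (SD, n = 3) in TpoTg hosts and 10.4 ± 3.05 (SD, n = 4) in WT hosts. Its log2 fold change was 0.87 (SE 0.113), with edgeR adjusted p = 0.0628, and it was 0.67 in the day 15 pair and 0.92 at day 19. The log2 fold change was 0.90 for Zc3h6, 0.99 for Kcnc3, 0.53 for Plaur, 0.40 for Mfsd4a, 0.35 for Napsa and 0.31 for Man2c1. Kcnc3 differed by 0.24 in the day 15 pair and by 1.24 at day 19. Plaur was at 29.1 CPM ± 2.97 (SD, n = 3) in TpoTg hosts and 20.2 ± 0.791 (SD, n = 4) in WT hosts, without overlap. Mcoln3 had a log2 fold change of -0.92 (SE 0.163), from 2.91 CPM ± 0.334 (SD, n = 3) in TpoTg hosts and 5.46 ± 0.336 (SD, n = 4) in WT hosts, also without overlap. Hsph1 had a log2 fold change of -0.58, with -0.19 in the day 15 pair and -0.75 at day 19. The genes called by DESeq2 were Napsa, Stoml1, Sesn1, Malat1 and Kdm7a, higher in TpoTg hosts, and Hsph1 and Hsp90b1, lower. Sesn1, Malat1 and Kdm7a were chosen after their values were seen. Without WT 381 all of the 10 genes but Man2c1 passed in edgeR, as did Sesn1 and Malat1. In a robust edgeR fit, Stoml1 and Chit1 passed, both with adjusted p = 0.0202.

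Platelet and megakaryocyte transcripts were higher as a list in the day 19 TpoTg hosts, although most were rare. In the comparison over both days, of 14 tested, 13 had a positive log2 fold change and 7 were higher when adjusted over the list alone, with a median of 1.08 (camera adjusted p = 7.39e-08; adjusted p = 0.448 with an estimated correlation). Itga2b (gene ID 16399, chromosome 11, 102453297 to 102469883) was at 6.27 CPM ± 3.56 (SD, n = 3) in TpoTg hosts and 1.89 ± 0.933 (SD, n = 4) in WT hosts. It was at 9.68 and 6.54 CPM in the day 19 TpoTg libraries and at 2.58 CPM in the day 15 TpoTg library. The WT libraries held 0.990 to 3.02 CPM. The host effect on the list differed between days (camera adjusted p = 1.64e-17; adjusted p = 0.157 with an estimated correlation). The log2 difference at day 19 was 2.38 for Itga2b, 2.56 for Clu, 2.02 for Ppbp, 1.65 for Gp1ba, 1.57 for Itgb3 and 1.62 for Pf4. In the day 15 pair it was -0.21, -0.19, -0.46, 0.05, -0.36 and -0.50 in the same order. The median of the list was 1.66 at day 19 alone, which the fits without TpoTg 385 (1.66) or WT 384 (1.63) in effect repeat. The list median was 0.77 without TpoTg 386 and 0.63 in female hosts alone. Its most abundant members, Nrgn and Sparc, chosen after their values were seen, had -0.31 and 0.05, with Nrgn at 21.9 CPM ± 3.94 (SD, n = 3) in TpoTg hosts and 26.8 ± 7.17 (SD, n = 4) in WT hosts. A stricter filter on low counts left 2 of its genes, so the list could not be tested among well expressed genes.

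**Figure D1:**
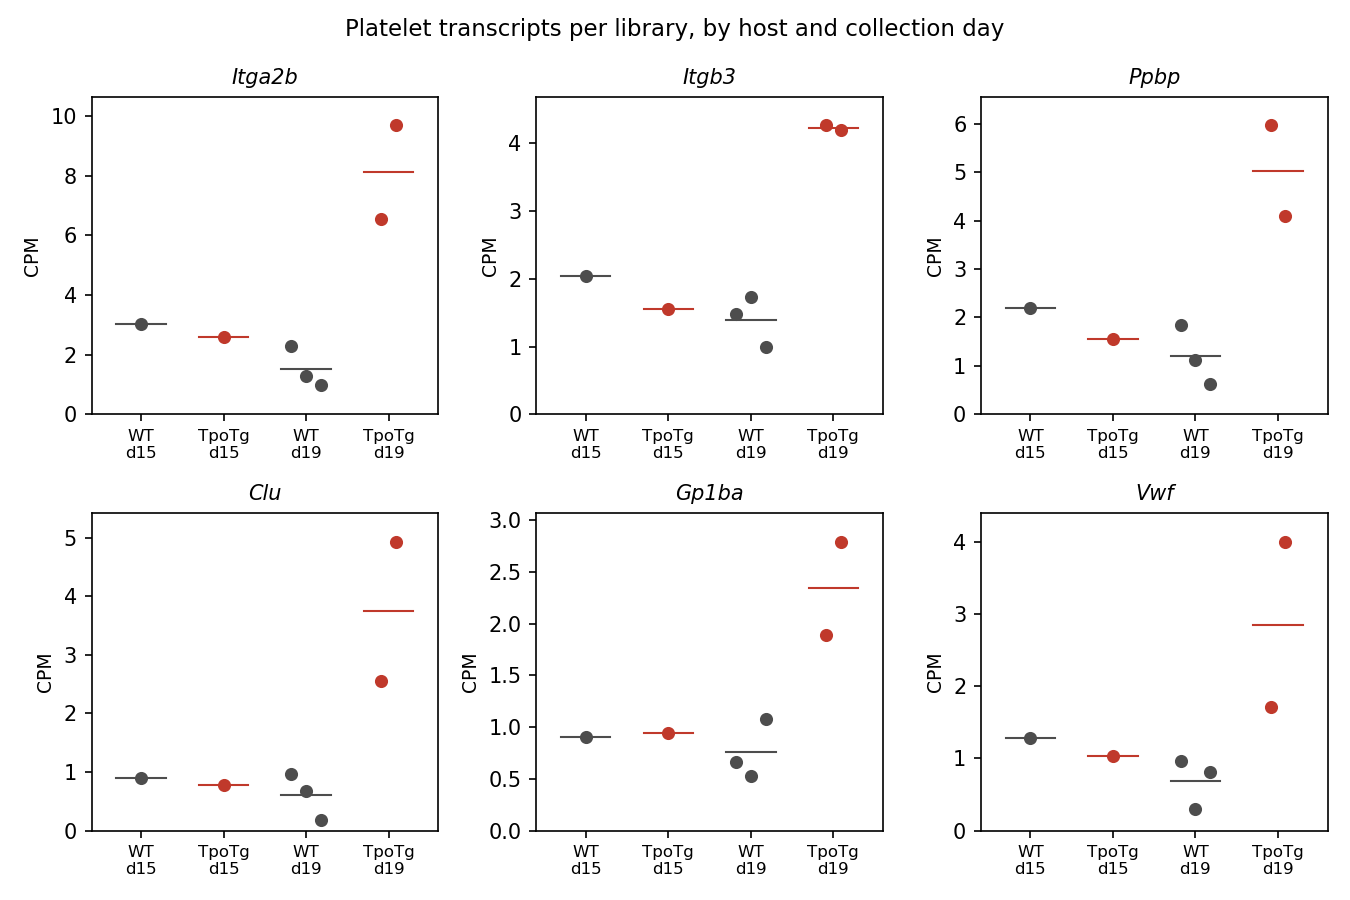
Platelet transcripts by host genotype and collection day, in CPM on the vertical axes (points are libraries and lines are means). Both day 19 TpoTg libraries lie above all WT libraries for the 6 genes, and the day 15 TpoTg library lies among them.

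Receptors for platelet products formed another list that was higher in TpoTg hosts, with 7 of 8 tested members positive and 3 higher when adjusted over the list alone (camera adjusted p = 2.97e-04; adjusted p = 0.343 with an estimated correlation). P2rx4 was at 15.4 CPM ± 0.723 (SD, n = 3) in TpoTg hosts and 11.8 ± 0.854 (SD, n = 4) in WT hosts, with a log2 fold change of 0.38 (SE 0.0976). Its difference was 0.33 in the day 15 pair and 0.41 at day 19. P2rx7 was at 8.61 CPM ± 0.596 (SD, n = 3) in TpoTg hosts and 5.79 ± 1.42 (SD, n = 4) in WT hosts, with a log2 fold change of 0.54 (SE 0.148), 0.25 in the day 15 pair and 0.68 at day 19. P2rx4 and P2rx7 did not overlap between the hosts. P2rx1, which platelets also express, had 1.31, and was chosen after its values were seen. Of the 3 dendritic cell genes tested, Flt3 had a log2 fold change of 1.51 (SE 0.315), from 13.97 CPM ± 6.84 (SD, n = 3) in TpoTg hosts and 4.76 ± 1.76 (SD, n = 4) in WT hosts, with 0.24 in the day 15 pair and 1.92 at day 19. Itgax had 0.54 and Xcr1 had -0.06 (camera adjusted p = 0.0233; adjusted p = 0.448 with an estimated correlation). The list of 3 pro-B and pre-B genes was lower in TpoTg hosts, with Il7r at -0.94, Vpreb3 at -0.33 and Sox4 at -0.16 (camera adjusted p = 0.00102; adjusted p = 0.343 with an estimated correlation), and 2 of them were lower when adjusted over the list alone. Without WT 381, Flt3 and Vpreb3 passed over all genes, with log2 fold changes of 1.26 and -0.25.

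Replication and protein-folding genes were lower in TpoTg hosts by small amounts in many genes. All 18 genes of the G1/S and DNA replication list had a negative log2 fold change, with a median of -0.14, and 10 were lower when adjusted over the list alone (camera adjusted p = 2.72e-10; adjusted p = 0.448 with an estimated correlation). Mcm4 (gene ID 17217, chromosome 16, 15623897 to 15637400) was at 241 CPM ± 44.9 (SD, n = 3) in TpoTg hosts and 268 ± 37.3 (SD, n = 4) in WT hosts. The log2 fold change was -0.22 (SE 0.0481) for Uhrf1, -0.20 (SE 0.0506) for Mcm5, -0.20 (SE 0.0497) for Mcm3 and -0.19 (SE 0.0452) for Mcm4. In the day 15 pair and at day 19, respectively, the differences were -0.18 and -0.21 for Mcm3, -0.15 and -0.21 for Mcm4, -0.09 and -0.25 for Mcm5 and -0.22 and -0.21 for Uhrf1. With the share of mitochondrial rRNA as a further covariate, chosen after the data were seen, the median of the replication list was -0.07, with 1 gene positive, and without TpoTg 378 it was -0.14, with 2 positive. In the unfolded protein and integrated stress list, 13 of 15 genes were negative and 5 were lower when adjusted over the list alone (camera adjusted p = 1.17e-06; adjusted p = 0.454 with an estimated correlation). Hsp90b1 had a log2 fold change of -0.29, Hspa5 -0.26, Pdia6 -0.21 and Calr -0.15. Hspa5 differed by -0.02 in the day 15 pair and by -0.36 at day 19. In the heat shock list 8 of 11 genes were negative and 6 were lower when adjusted over the list alone (camera adjusted p = 2.97e-04; adjusted p = 0.448 with an estimated correlation), with Chordc1 at -0.25, Dnaja1 at -0.20 and Hsp90aa1 at -0.19. MYC targets had a median of -0.08, with 24 of 25 negative and 0 called when adjusted over the list alone (camera adjusted p = 2.08e-06; adjusted p = 0.485 with an estimated correlation). Without TpoTg 386 that median was -0.05, with 4 genes positive. Without WT 381, Uhrf1, Hsp90b1 and Hsp90aa1 passed over all genes, with log2 fold changes of -0.23, -0.26 and -0.22. Hspe1 had -0.22, Hspd1 -0.19, Odc1 -0.15 and Nolc1 -0.14.

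**Figure D2:**
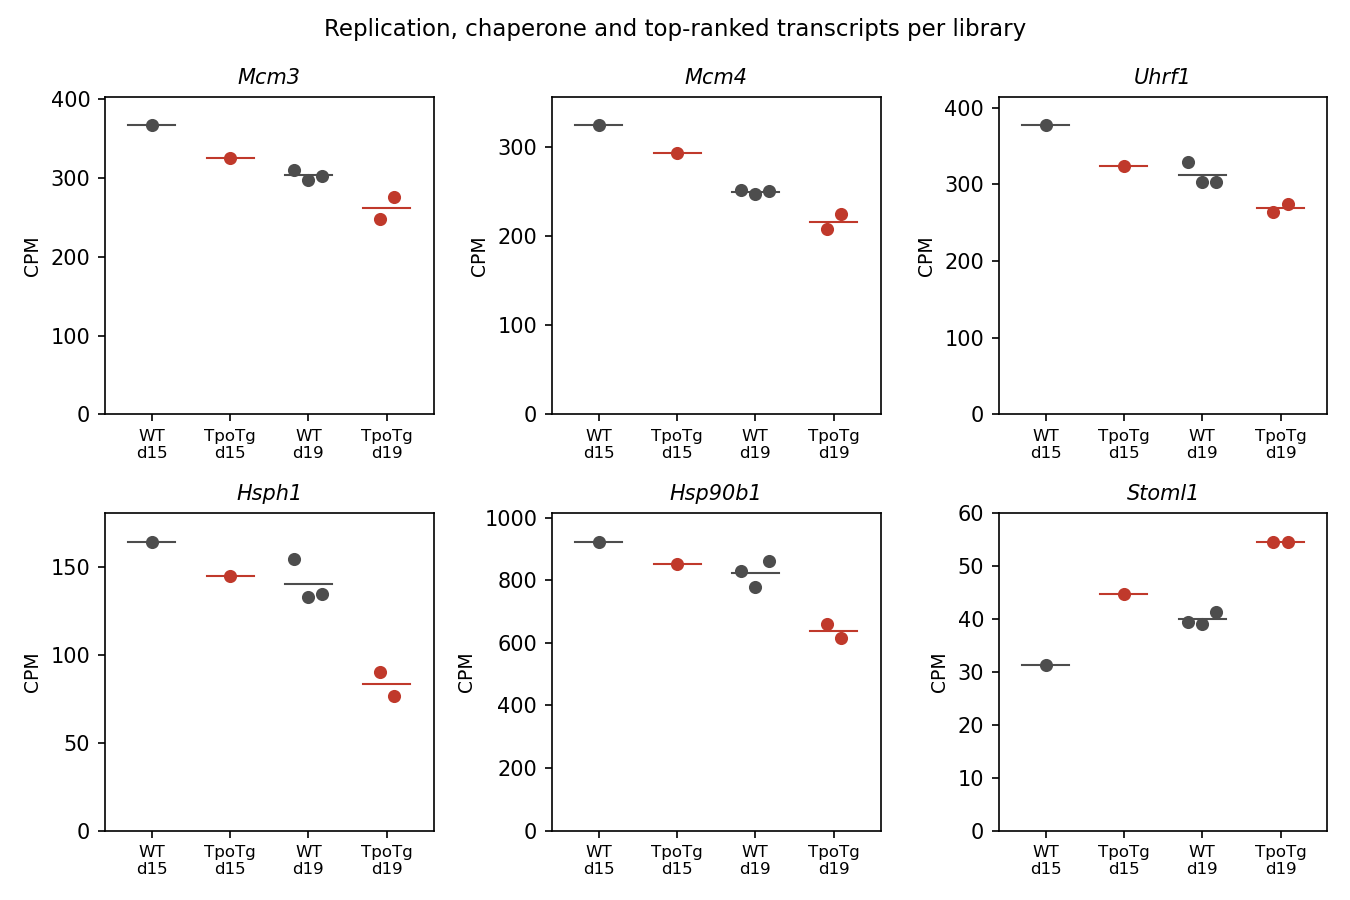
Replication genes (Mcm3, Mcm4, Uhrf1), chaperone genes (Hsph1, Hsp90b1) and Stoml1 by host genotype and collection day, in CPM on the vertical axes (points are libraries and lines are means). Within each day the TpoTg mean is lower for the first 5 genes and higher for Stoml1.

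A set of 3 further lists were called higher in TpoTg hosts with the preset correlation. All 8 mitochondrially encoded genes tested were positive, with a median of 0.13 (camera adjusted p = 0.0145; adjusted p = 0.541 with an estimated correlation), and mt-Nd1 had 0.14. Of 15 cholesterol synthesis genes, 14 were positive, with a median of 0.08 (camera adjusted p = 0.0425; adjusted p = 0.64 with an estimated correlation), and Hmgcs1 had 0.17. All 8 tested RNAs that lack a usual poly(A) tail were positive, with a median of 0.98 (camera adjusted p = 2.97e-04; adjusted p = 0.454 with an estimated correlation), and H1f4 had 1.11 (SE 0.263), which passed without WT 381 at 1.41. The median of the RNAs without a usual tail was 0.58 without TpoTg 386, 0.63 without WT 375 and 1.58 without WT 381, with 1 RNA negative in each case. With the share of mitochondrial rRNA as a covariate, chosen after the data were seen, the median was 0.06 for the mitochondrial list with 7 of 8 positive, 0.06 for cholesterol with 12 of 15 positive and 0.12 for the RNAs without a usual tail with 5 of 8 positive. These 3 lists and the dendritic list were then not called, and 7 other lists were. The cholesterol median was 0.16 at day 19 alone, which the fits without TpoTg 385 or WT 384 (0.16 in each) in effect repeat. It was 0.05 without TpoTg 386 or WT 375. The dendritic call was lost without TpoTg 386, WT 375 or TpoTg 378, and the list was not tested without WT 377 or WT 381, where 32 lists were. The mitochondrial call was lost without TpoTg 386 or WT 375, and the cholesterol one without TpoTg 386, WT 375, TpoTg 378, WT 377 or WT 381. Of 33 lists tested, 11 were called, and fry called 0. The other 22 lists had camera adjusted p values from 0.0802 to 0.959. They included neutrophils (median 0.04), monocytes and macrophages (0.15), B lineage identity (-0.0033), B cell receptor signalling (-0.0042), p53 targets (-0.05), interferon response (0.02) and the pro-survival (0.02) and pro-apoptotic (0.05) BCL2 families. Of these 22, camera called interferon response (adjusted p = 0.00251) and plasma cells (0.0498) without TpoTg 378, and G2 and mitosis without TpoTg 386 (0.00346) or WT 381 (2.23e-06). It called red cells without TpoTg 386 (4.91e-08) or WT 377 (7.38e-04). It called monocytes and macrophages (0.0384 to 0.0423) and nuclear oxidative phosphorylation (0.0105 to 0.0310) without TpoTg 385, WT 384 or TpoTg 378. The fits without TpoTg 385 or WT 384 both in effect repeat day 19 alone. With an estimated correlation and by fry, 0 host lists were called without any one library. Red cell genes had a median of -1.61, with 3 of 4 lower when adjusted over the list alone, and these 3 had their highest values in WT 384. The red cell median was -0.17 at day 19 alone, which the fits without WT 384 (-0.16) or TpoTg 385 (-0.17) in effect repeat.

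The count of genes between hosts depended on WT 381 and on the model. Without WT 381, edgeR called 69 genes, 57 higher and 12 lower in TpoTg hosts, while leaving out any other library gave 0. The fits without TpoTg 385 or WT 384 are in effect both that of day 19 alone. Without WT 381 and with host sex in the model it called 217. With WT 381 kept, it called 111 with the share of mitochondrial rRNA as a covariate and 14 with no filter on low counts, and DESeq2 called 7. The covariate and the fit with host sex were chosen after the data were seen. Of the 69, 2 were the mitochondrial rRNAs, 5 were from the list of RNAs without a usual poly(A) tail and 6 were gene IDs without a symbol, and of the 10 with the smallest p, 2 were mitochondrial rRNAs and 3 had no symbol. The 69 also included Stoml1, Chit1, Kcnc3, Plaur, Napsa, Flt3, Hsph1 and Uhrf1. Lifr and S100a6 were among them too and were chosen after their values were seen. Over all 7 libraries Lifr was at 148 CPM ± 26.1 (SD, n = 3) in TpoTg hosts and 73.0 ± 23.3 (SD, n = 4) in WT hosts, and S100a6 at 250.3 CPM ± 36.3 (SD, n = 3) in TpoTg hosts and 146 ± 54.3 (SD, n = 4) in WT hosts, both without overlap. Their log2 fold changes were 1.01 and 0.78 with all libraries and 0.80 and 0.54 without WT 381. WT 381 was also the WT library with the largest share of RNA that lacks a usual poly(A) tail. Mitochondrial rRNA (mt-Rnr1 and mt-Rnr2) took 0.308% of its counts (95% Wilson interval 0.305 to 0.311), against 0.0912% (0.0896 to 0.0929) in WT 375, 0.113% (0.111 to 0.115) in WT 377 and 0.114% (0.112 to 0.116) in WT 384. The share was 0.158% (0.156 to 0.160) in TpoTg 385, 0.278% (0.274 to 0.281) in TpoTg 386 and 0.279% (0.276 to 0.282) in TpoTg 378. Between hosts it was 0.238% ± 0.0693 (SD, n = 3) in TpoTg and 0.157% ± 0.102 (SD, n = 4) in WT, with a 2-sided exact permutation p = 0.229. The smallest p that 3 against 4 libraries allow is 0.0571.

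**Figure D3:**
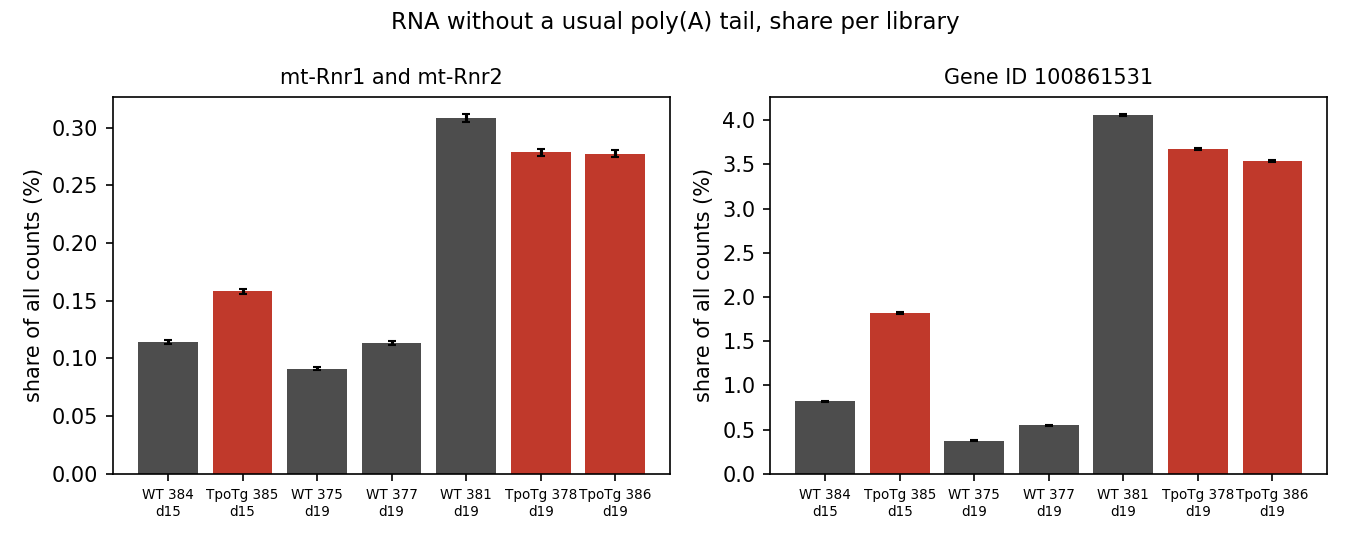
Share of all counts, in percent, taken by mt-Rnr1 and mt-Rnr2 together (left) and by gene ID 100861531, which has no symbol in the annotation used (right), per library (grey bars are WT, red bars TpoTg; error bars are 95% Wilson intervals). WT 381 lies with the day 19 TpoTg libraries in both panels.

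The comparison of day 19 with day 15 asked how the lymphoma cells changed as disease advanced. Interferon-induced genes fell and were lower at day 19 in both host genotypes, and transcripts of neutrophils and monocytes fell with them. Replication genes and several MHC class I genes also fell, while the NF-kB subunit genes Nfkb2 and Relb rose. With all 7 libraries, none of the lists that camera called between days was called when the correlation between genes was estimated. edgeR called 665 of 11220 genes, 236 that rose and 429 that fell, with a median absolute log2 fold change of 0.42. The largest source of variation among libraries, 35.8% of the variance, placed both day 15 libraries apart from all 5 day 19 libraries. The count was 61 without WT 384, 86 without TpoTg 385, 313 without TpoTg 378, 356 without WT 377 and 1313 without WT 381. With host sex as a further covariate it was 288, and within female hosts 1166. The 2 day 15 hosts were both female and were bled on a single date, so the day after transplant and the collection date cannot be told apart.

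Interferon-induced genes had the smallest camera p among the lists between days. All 17 tested were negative, and 15 passed, both over all genes and adjusted over the list alone. The median log2 fold change was -1.29 (camera adjusted p = 4.01e-41, adjusted p = 0.0776 with an estimated correlation, and fry adjusted p = 0.00871). With an estimated correlation the list was called without TpoTg 378 (adjusted p = 0.0126), and by fry it was not called without WT 384 (adjusted p = 0.0675), with the share of mitochondrial rRNA in the model (0.0543) or within female hosts (0.0502). Usp18 (gene ID 24110, chromosome 6, 121245906 to 121270917) went from 6.06 CPM ± 0.915 (SD, n = 2) at day 15 to 0.924 ± 0.304 (SD, n = 5) at day 19, a log2 fold change of -2.72 (SE 0.255) with edgeR adjusted p = 4.19e-04. Rtp4 fell from 12.2 CPM ± 0.911 (SD, n = 2) at day 15 to 1.96 ± 1.02 (SD, n = 5) at day 19, with a log2 fold change of -2.65 (SE 0.269). Tlr7 fell by 2.71 on the log2 scale and Ifi213 by 2.72. Isg15 fell by 2.09, Oasl2 by 1.51 and Stat1 by 0.68. Slfn5, Mx1 and Oas2, chosen after their values were seen, had log2 fold changes of -1.89, -2.09 and -1.92. The calls of Usp18, Mx1, Oas2 and Slfn5 held without any library in turn. The edgeR call was lost, with adjusted p in parentheses, for Rtp4 and Tlr7 without WT 384 (0.0524 to 0.0814), and Oasl2 and Stat1 without TpoTg 385 or WT 384 (0.12 to 0.26). Irf7 did not pass, at -0.20.

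**Figure D4:**
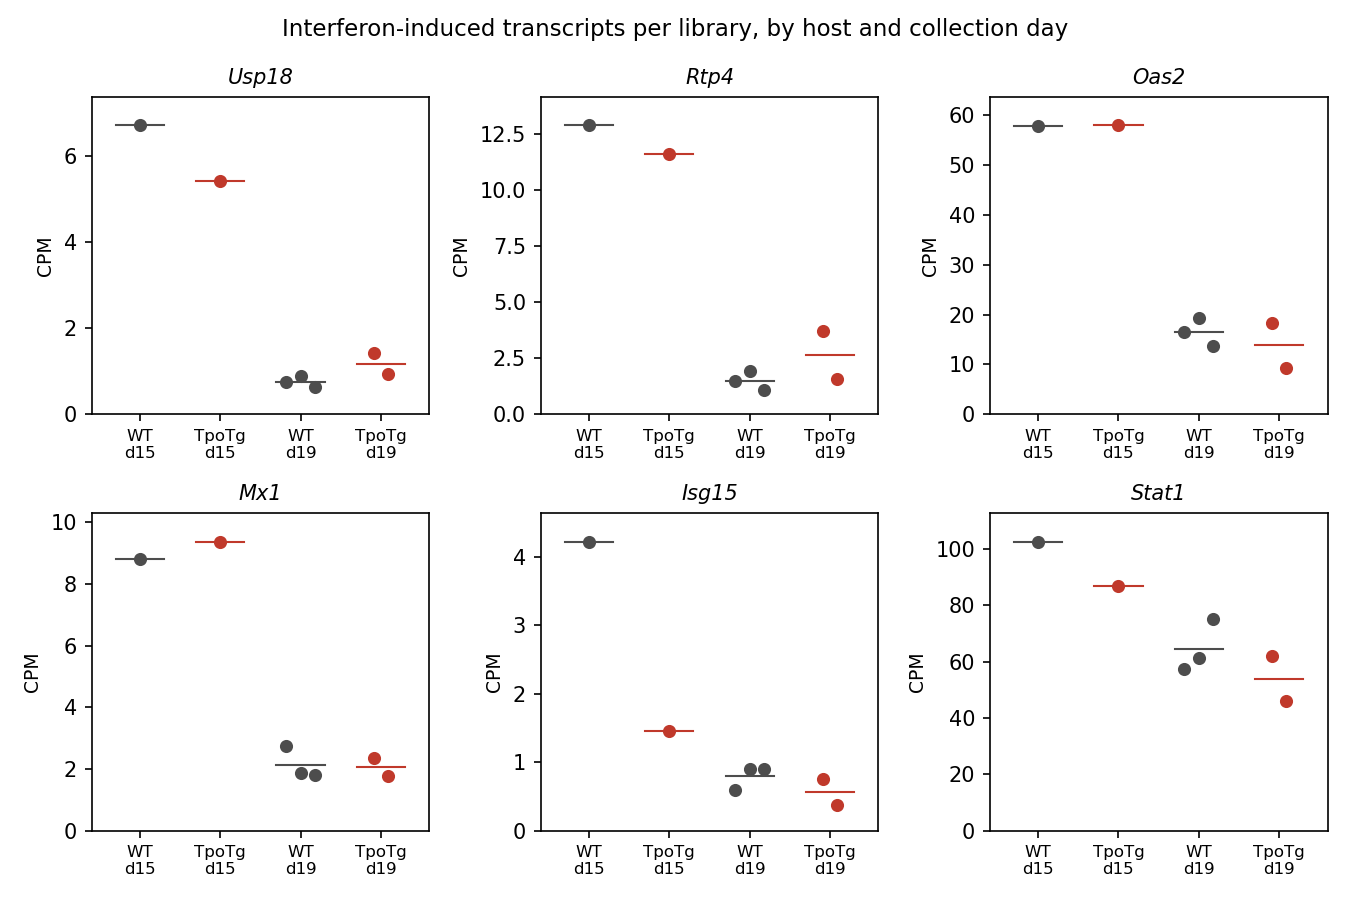
Interferon-induced transcripts by host genotype and collection day, in CPM on the vertical axes (points are libraries and lines are means). For each of the 6 genes both day 15 libraries lie above all day 19 libraries.

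Transcripts of other blood cells fell between the days. All 11 neutrophil genes were negative, with a median of -0.79. Of these, 6 passed over all genes and 9 when adjusted over the list alone (camera adjusted p = 2.29e-10, and adjusted p = 0.23 with an estimated correlation). S100a8 fell from 30.9 CPM ± 1.97 (SD, n = 2) at day 15 to 17.7 ± 2.27 (SD, n = 5) at day 19, with a log2 fold change of -0.80 (SE 0.12). Mmp9 had -1.10, Ltf -1.09 and Ngp -0.79. Of 7 monocyte and macrophage genes, 6 were negative, 4 passed as lower over all genes and 5 when adjusted over the list alone (camera adjusted p = 2.04e-04, and adjusted p = 0.221 with an estimated correlation). Itgam had -1.08 and Lyz2 -0.99. Ly6c2 and Csf1r, chosen after their values were seen, had -1.11 and -0.80. Without WT 384, which leaves 1 library at day 15, Lyz2 was at -0.32, and Itgam, Ly6c2 and Csf1r at -1.02, -0.91 and -0.94. The edgeR call was lost, with adjusted p in parentheses, for S100a8 without WT 384 (0.15), and Mmp9 and Itgam without TpoTg 385 or WT 384 (0.0537 to 0.219). It was also lost for Ltf without TpoTg 385, WT 384, WT 375, TpoTg 378 or WT 377 (0.0551 to 0.43), and Ngp without TpoTg 385, WT 384, TpoTg 378 or WT 377 (0.0511 to 0.264). Other losses were those of Lyz2 without WT 384, TpoTg 386 or WT 377 (0.062 to 0.558), and Ly6c2 and Csf1r without TpoTg 385, WT 384, TpoTg 386, TpoTg 378 or WT 377 (0.067 to 0.343). Of the 4 red cell genes tested in the list, 3 fell and the other had 0.15 and did not pass (camera adjusted p = 7.39e-04, and adjusted p = 0.317 with an estimated correlation). The 4 red cell genes named next all fell, so they are not the same 4. Hbb-bs was at 18.7 CPM ± 18.9 (SD, n = 2) at day 15 and 1.70 ± 1.17 (SD, n = 5) at day 19, with -3.55, and Hba-a2, Hbb-b1 and Alas2 had -2.84, -2.84 and -2.98. Without WT 384, which held 69.5 CPM of Hba-a2, the calls of these 4 genes and of the list were lost, with 1 library left at day 15. The log2 fold changes were then -2.11 for Hbb-bs, -1.11 for Hba-a2, -1.13 for Hbb-b1 and -0.92 for Alas2. Globin genes have near-identical copies, so the values of single globin genes are uncertain. Platelet transcripts did not pass as a list between days, with a median of 0.28 against a mean of 0.15 and camera adjusted p = 0.882. Camera with the preset correlation called them in opposite directions, lower at day 19 without TpoTg 385 and higher without WT 384. Neither call was made with an estimated correlation. Each of these fits compares the 1 library left at day 15 with the day 19 libraries of its own genotype. The calls therefore do not show a change between days shared by both genotypes.

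All 18 replication genes were negative between the days. Of these, 11 passed over all genes and 15 when adjusted over the list alone (camera adjusted p = 8.67e-13, and adjusted p = 0.23 with an estimated correlation). Mcm4 fell from 308 CPM ± 22.2 (SD, n = 2) at day 15 to 236 ± 19.3 (SD, n = 5) at day 19, with a log2 fold change of -0.41 (SE 0.0482). Mcm3, Mcm5 and Uhrf1 fell by 0.29, 0.34 and 0.27. In MHC class I presentation 10 of 11 genes were negative, and 7 were lower when adjusted over the list alone (camera adjusted p = 2.04e-04, and adjusted p = 0.338 with an estimated correlation). Over all genes 3 passed, Psmb9, Tap1 and B2m. Their log2 fold changes were -0.32, -0.47 and -0.32. Ccr7, Gpr183 and Itgal fell in the homing list by 0.37, 0.89 and 0.57 (camera adjusted p = 7.99e-04; adjusted p = 0.23 with an estimated correlation), and 5 members were lower when adjusted over the list alone. In the JAK-STAT list 7 of 9 genes were negative (camera adjusted p = 0.0145, and adjusted p = 0.248 with an estimated correlation). Of these, 2 passed, both over all genes and adjusted over the list alone. Ccnd3 and Osm fell by 0.59 and 0.63. Immune checkpoint ligands were called lower, with 0 of 7 passing over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0136; adjusted p = 0.23 with an estimated correlation). The edgeR call was lost, with adjusted p in parentheses, for Mcm4 without TpoTg 385 (0.0532), and Mcm3, Mcm5, Tap1, Gpr183 and Ccnd3 without TpoTg 385 or WT 384 (0.0524 to 0.201). It was also lost for Uhrf1 without TpoTg 385, WT 384 or TpoTg 378 (0.0559 to 0.191), and Psmb9 without TpoTg 385, WT 384, TpoTg 378 or WT 377 (0.0514 to 0.257). Other losses were those of B2m without TpoTg 385, WT 384 or WT 377 (0.0545 to 0.246), and Ccr7, Itgal and Osm without TpoTg 385, WT 384, TpoTg 386, TpoTg 378 or WT 377 (0.0501 to 0.355). The checkpoint list was not called without WT 384 (camera adjusted p = 0.088). Tap1, B2m, Gpr183, Itgal and Osm were chosen after their values were seen.

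Genes that rose by day 19 with the largest fold changes were mostly rare. Col5a3 (gene ID 53867, chromosome 9, 20770050 to 20815117) rose from 16.2 CPM ± 3.38 (SD, n = 2) at day 15 to 80.2 ± 52.2 (SD, n = 5) at day 19, with a log2 fold change of 2.22 (SE 0.492) and adjusted p = 0.0264. Ndrg1 rose from 1.08 CPM ± 0.0703 (SD, n = 2) at day 15 to 3.47 ± 0.974 (SD, n = 5) at day 19, with 1.69 (SE 0.307). Kndc1, Fxyd7, Snord43, Gadd45g and Nrxn2 rose by 1.67, 1.56, 1.53, 1.51 and 1.45 on the log2 scale. Txnip, chosen after its values were seen, rose from 118 CPM ± 5.70 (SD, n = 2) at day 15 to 215 ± 16.6 (SD, n = 5) at day 19, with 0.87 (SE 0.0669). In the list of RNAs without a usual poly(A) tail, all 8 genes were positive. Over all genes 2 passed (Rpph1 at 1.05 and H1f2 at 0.55), and 6 when adjusted over the list alone (camera adjusted p = 4.53e-06, and adjusted p = 0.284 with an estimated correlation). The median was 1.08. With the share of mitochondrial rRNA as a covariate, chosen after the data were seen, it was 0.34, with 1 RNA negative. All 8 lay above both day 15 libraries in TpoTg 386, TpoTg 378 and WT 381, but 3 did in WT 375 and 4 in WT 377. Nfkb2 and Relb rose by 0.42 and 0.52 in the NF-kB list, and 3 members were higher when adjusted over the list alone (camera adjusted p = 0.0243; adjusted p = 0.237 with an estimated correlation; 0.083 without WT 384). All 30 ribosomal protein genes were positive, with a median of 0.22, and of 0.13 with host sex as a covariate. Of these, 1 passed over all genes (Rps28, 0.29) and 29 adjusted over the list alone (camera adjusted p = 4.15e-09; adjusted p = 0.547 with an estimated correlation). Rpph1, H1f2, Nfkb2, Relb and Rps28 were chosen after their values were seen. The edgeR call was lost, with adjusted p in parentheses, for Col5a3 without TpoTg 385, WT 384 or TpoTg 378 (0.0714 to 0.264), and Ndrg1 and Nfkb2 without TpoTg 385 or WT 384 (0.0635 to 0.285). It was also lost for Kndc1 and Snord43 without TpoTg 385, WT 384, TpoTg 386 or TpoTg 378 (0.0502 to 0.268), and Fxyd7, Gadd45g and Relb without TpoTg 385, WT 384, TpoTg 386, WT 375, TpoTg 378 or WT 377 (0.0522 to 0.33). Other losses were those of Nrxn2, H1f2 and Rps28 without TpoTg 385, WT 384, TpoTg 386, TpoTg 378 or WT 377 (0.0652 to 0.376). In all, 12 of 33 lists were called with the preset correlation, 0 with an estimated one and 10 by fry. The fry count was 0 without WT 384, 4 without TpoTg 385, 4 without TpoTg 386, 7 without WT 375, 2 without TpoTg 378, 3 without WT 377 and 13 without WT 381, and 0 within female hosts. The other 21 lists had camera adjusted p values from 0.075 to 0.929. Of these 21, camera called MHC class II presentation, immediate early genes and p53 targets (5.02e-04 to 0.0138) and B cell receptor signalling (0.0412) without WT 381. Further calls came from fits that keep 1 library at day 15. These were the platelet and cholesterol lists without TpoTg 385 or WT 384, and MHC class II, immediate early, p53 and unfolded protein lists without WT 384. The platelet and cholesterol lists were lower at day 19 without TpoTg 385 and higher without WT 384. None of the calls gained without these libraries was made with an estimated correlation.

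The comparison of male with female hosts asked whether host sex marked the transplanted cells. edgeR called 0 of 11220 genes, with 1059 at an unadjusted p under 0.05 and a smallest adjusted p of 0.150. DESeq2 called 9 genes and limma-voom 0, with 1045 at an unadjusted p under 0.05. The 6 genes with the smallest p, none of which passed, were H2-Eb2, Ccnd2, Sorcs2, Dnah8, Serpinb1a and Cpm (carboxypeptidase M). Their log2 fold changes, male against female hosts, were -0.58, -0.75, -0.48, -0.38, 0.40 and -1.04. Without WT 377 the count was 6 genes, and without WT 381 it was 22. Xist was at 2112, 1925 and 1901 CPM in the male hosts TpoTg 378, WT 377 and WT 381. The test of whether the host effect differed between days called 0 genes, with 368 at an unadjusted p under 0.05 and a smallest adjusted p of 0.996. DESeq2 also called 0 there, with 70 at an unadjusted p under 0.05, and without WT 381 edgeR called 6. Only 1 library per genotype was taken at day 15, so the spread in that test came from day 19.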

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

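Chosen after the results were seen were the list tests of the host effect by day, the splits of the libraries without WT 381, and the tests of explanations, whereas the splits of all 7 libraries were planned. A library was singled out when its gap to the nearest other library of its group, as a share of the group's range, exceeded Dixon's 95% critical value. This happened in 16 of 120 groups tested, and chance gives about 1 in 20.

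WT 381 stood apart from the other WT libraries in RNA content. Gene IDs without a symbol took 4.81% of its counts, against 0.718 to 1.19%, and its most abundant gene took 4.05%, against 1.075 to 1.141%. Mitochondrial rRNA took 0.308%, against 0.0912 to 0.114%. Among genes, H4c4 was at 4.68 CPM, against 0.590 to 0.976, and Cd19 at 1051 CPM, against 871 to 900.3. At day 19, Col5a3 was at 171 CPM in WT 381, against 44.1 to 69.9 in the other 4 libraries, and Ly6c2 at 0.720 CPM, against 1.35 to 1.49.

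Non-polyadenylated RNA was high in the TpoTg libraries and in WT 381. In WT 381, 7 of the 8 such RNAs tested were higher than in each other WT library. This count is the pattern itself, so RNA without a poly(A) tail that passed through library preparation stays open as a candidate explanation, without a test that supports it. A TpoTg library wrongly labelled WT 381 stays open too, and the 69 genes called between hosts without it cannot decide this. Of these, 29 were nearer to the day 19 TpoTg mean in WT 381 than to the mean of the other day 19 WT libraries (on CPM with 0.1 added). That is within 2 binomial standard errors of an even division, but this error takes the genes as independent. The 69 also include mitochondrial rRNAs and RNAs without a usual poly(A) tail, which are the pattern itself. Several single genes followed the WT label, with WT 381 at 2.16 CPM of Flt3 against 16.7 and 19.0 in the day 19 TpoTg libraries, and at 0.990 CPM of Itga2b against 6.54 and 9.68, 27.2 CPM of Kcnc3 against 72.9 and 88.5 and 20.2 CPM of Plaur against 30.8 and 30.9, but single genes do not exclude a wrong label. The host transgene cannot be told apart from these, with an exact permutation p of 0.229 for the mitochondrial rRNA share, where 0.0571 is the smallest p the design allows.

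WT 384, the day 15 WT library, had 69.5 CPM of Hba-a2, against 3.15 to 7.82 in the other WT libraries, and 32.1 CPM of Hbb-bs, against 0.750 to 3.33. It also had the highest Mcm4 among WT libraries (324 CPM, against 246 to 251) and the highest Ngp (7.39 CPM, against 3.54 to 4.14). It was the lone WT library at day 15, so day and library are not separable in these values. WT 375 had 0.959 CPM of P2rx1, against 0.150 to 0.226, 13.1 CPM of P2rx4, against 11.2 to 11.5, and 2111 CPM of Xist, against 1901 to 1934. WT 377 had 24.4 CPM of Sc5d, against 26.7 to 27.2. At day 19, TpoTg 386 had 2.98 CPM of Ltf, against 1.201 to 1.705.

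The effect of the host differed between the days for 11 lists, by camera on the interaction term with a preset correlation. With an estimated correlation, and by fry, 0 lists were called. The adjusted p was 1.64e-17 for platelets and megakaryocytes (median interaction log2 fold change 2.11), 1.22e-08 for cholesterol synthesis, 5.46e-07 for red cells, 0.00336 for G2 and mitosis, 0.00453 for the unfolded protein list and 0.00684 for ribosomal proteins. It was 0.0161 for dendritic cells, 0.0170 for nuclear oxidative phosphorylation, 0.0170 for MHC class II presentation, 0.0209 for MYC targets and 0.0479 for neutrophils. Each day 15 value came from 1 library per genotype.

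Platelet transcripts were higher in the day 19 TpoTg libraries. At day 15 the CPM of the platelet list summed to 53.04 in TpoTg 385 and 61.38 in WT 384. A lower purity of the sort for all other blood cells alike is argued against by the neutrophil genes tested, and only by these. The neutrophil list had a mean log2 fold change of 0.0537 (SE over genes 0.0656). The platelet list had 0.945 (SE over genes 0.177), a difference of 0.891 (SE 0.189). At day 19 alone, the neutrophil mean was 0.151 (SE over genes 0.0760) and the platelet mean 1.54 (SE over genes 0.231). Camera with the preset correlation also called dendritic cells (adjusted p = 3.55e-04) and monocytes and macrophages (0.0422) higher at day 19. Neither was called with an estimated correlation (adjusted p = 0.332 and 0.439), and the red cell median was -0.17. Carry-over of host cells other than neutrophils stays open. SEs of list means take the genes as independent and do not measure the spread between hosts. The non-polyadenylated RNA content was examined only through the mitochondrial rRNA share, as a single covariate. With that share in the model the platelet median was 1.04, against 1.08 without it. The mean was 0.953 (SE 0.229), with 11 of 14 positive, so the size of the difference hardly changed. The camera call with the covariate (adjusted p = 8.23e-04) cannot decide this. It was not made with an estimated correlation (adjusted p = 0.592, and 0.448 without the covariate). Platelets or their RNA carried with the sorted cells, which a CD19 and mCherry gate would not remove if bound to them, stay open as a candidate explanation, as does expression by the lymphoma cells themselves, and no test told them apart. That 13 of 14 platelet transcripts were positive, Itga2b at up to 9.68 CPM and the exception Nrgn at 21.9 CPM in TpoTg hosts, is the pattern itself. Chance was not excluded, and the share of splits is not a clean measure of it. In 9 of 35 splits, the real one included, the mean was at least as far from 0 as 0.945 in either direction, up to 1.44 in size. Some of these keep the real division of the day 19 libraries. TpoTg 378, TpoTg 386 and WT 384 against the rest gave 1.13, and WT 375, WT 377 and WT 381 against the rest gave -1.42. Others break that division, the largest among them. TpoTg 378, TpoTg 386 and WT 375 against the rest gave 1.44, and TpoTg 385, WT 381 and WT 384 against the rest gave -1.35. Groupings other than that by host thus gave platelet differences as large.

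The counts of genes and lists between hosts were set against other splits of the 7 libraries into 3 and 4, planned before the results were seen, and without WT 381. For genes, the real split gave 0, which all 35 splits reach by definition, so the splits do not bear on chance there. The highest gave 195, for TpoTg 385, WT 381 and WT 384 against the rest. With collection day in the model, that split sets WT 381 alone against the other 4 day 19 libraries, so it points to a structure of the samples in which WT 381 stands apart. For lists, 16 of 35 splits gave as many as the real 11, up to 14, so chance was not excluded. These too include splits that keep the real division of the day 19 libraries, so the share is not a clean measure of chance. The splits with 14 lists break that division. They were TpoTg 385, WT 377 and WT 381 against the rest, and TpoTg 378, TpoTg 386 and WT 377 against the rest. Groupings other than that by host thus gave as many list calls at the preset correlation. Between sexes the real split gave 0, which all 34 splits that could be fitted reach by definition. The highest gave 336, for the same split and for WT 375, WT 377 and WT 384 against the rest, both of which isolate WT 381 once day and genotype are in the model. Without WT 381 the real split gave 69 genes and the highest of the other splits 9, with 1 of 10 as large, and 10 splits are too few for a share under 0.05.

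Interferon genes were lower at day 19. The sex of the hosts is argued against, since within the 4 female hosts the median was -1.74 and the mean -1.74 (SE 0.242), with all 19 tested genes negative (camera adjusted p = 1.98e-55; adjusted p = 0.654 with an estimated correlation and 0.0502 by fry, against 0.0776 and 0.00871 over all hosts). A larger share of host neutrophils and monocytes at day 15, with unchanged profile, is argued against for the genes tested. The interferon list had a mean of -1.43 (SE over genes 0.201). The neutrophil and monocyte lists together had -0.708 (SE over genes 0.0853), a difference of -0.718 (SE 0.218). All SEs of list means here take the genes as independent and do not measure the spread between hosts. A response of the lymphoma cells that faded, activated host cells at day 15, and the collection date may each explain the pattern and stay open.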

How the results depend on the processing

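The share of mitochondrial rRNA as a covariate, the fit without WT 381 with host sex, and the day lists without each library or within females were chosen after the data were seen. Between hosts, edgeR's 0 genes stayed at 0 with RLE and upper quartile factors, limma-voom, the stricter filter, receptor segments left out, no covariate, day and sex as covariates, and day 19 alone. They became 7 with DESeq2, 14 with no filter, 89 in female hosts alone, 2 with a robust fit, 111 with the mitochondrial rRNA share as a covariate and 217 without WT 381 with host sex in the model. Leaving out each library gave 0 to 69, with 69 without WT 381. Between days, the 665 genes became 288 with host sex as a covariate and 1166 in female hosts alone, and 61 to 1313 without each library. Where a day 15 library was left out, the lone remaining one was assumed to vary like the others, and fewer samples lower the power. Between sexes, the 0 genes became 9 with DESeq2, 144 with no filter and 0 to 22 without each library. The interaction gave 0 to 6 without each day 19 library. The 11 host lists became 0 with an estimated correlation and 0 with fry, and the 12 day lists became 0 with an estimated correlation. By camera with the preset correlation, the counts of lists ranged from 8 to 14 for hosts and from 12 to 18 for days. By fry the day lists numbered 10 in the main fit, 0 within female hosts and 13 without WT 381. Genes with host differences near 0 changed sign. Day 19 alone gave Cd19 -0.0763 and Mcl1 -0.0020, female hosts alone gave Cd79a 0.0190 and Sparc -0.14, day and sex as covariates gave Xcr1 0.0070, Bcl2l1 -0.0025 and Sparc -0.0019, and the fit without WT 381 with host sex gave Sparc -0.0817. The mitochondrial rRNA covariate gave Myc -0.0410 and Cd19 -0.0688. Without each library the values ran from -0.0767 to 0.0772 for Cd19, -0.0024 to 0.0294 for Mcl1, -0.21 to 0.0805 for Xcr1, -0.0664 to 0.11 for Bcl2l1 and -0.0938 to 0.18 for Sparc. For changes other than those from fewer samples, the cause was not tested. Of the other values of single genes between hosts, 1208 kept direction and side of the threshold and 109 newly passed. Between days 683 were kept, 174 no longer passed and 7 newly passed, and between sexes 78 were kept and 18 newly passed. The alternative scalings moved the median of all genes by under 0.01, and the platelet list could not be tested under the stricter filter, which left 2 of its genes. The groups share no replicate numbers, so none served as a block, and the fit without WT 381 with host sex sets 1 TpoTg library against 1 WT library for each combination of day and sex. At 10859727 to 13214986 counts per library, most platelet transcripts had few counts, and genes under the floor could not be compared.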

Other observations

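The gene with the largest share of counts in WT 381 was gene ID 100861531, which has no symbol in the annotation used. It took 4.05% of counts there (95% Wilson interval 4.04 to 4.07), 3.54% (3.53 to 3.55) in TpoTg 386, 3.67% (3.66 to 3.69) in TpoTg 378 and 1.82% (1.81 to 1.83) in TpoTg 385. It took 0.821% (0.816 to 0.826) in WT 384, 0.375% (0.372 to 0.379) in WT 375 and 0.549% (0.545 to 0.553) in WT 377. Gene IDs without a symbol together took 3.70% ± 1.20 (SD, n = 3) of counts in TpoTg hosts and 1.92% ± 1.94 (SD, n = 4) in WT hosts, with a 2-sided exact permutation p = 0.229. The total count was 10859727 to 11390468 in the TpoTg libraries and 11660711 to 13214986 in the WT libraries, with a 2-sided exact permutation p = 0.0571, the smallest the design allows. The CPM of the platelet list summed to 66.5 ± 14.6 (SD, n = 3) in TpoTg hosts and 49.3 ± 10.2 (SD, n = 4) in WT hosts, with a 2-sided exact permutation p = 0.114. These comparisons were chosen after the data were seen.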
